A study of Mus musculus with 4 samples.

How the data were processed

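The data are RNA-seq gene counts from 4 individual chimeric mouse embryos staged at E7.75, 2 carrying ESCs with inducible FLAG-Lhx1 and 2 with FLAG-Lhx1-mt. Per the labels' protocols, the ESCs were grown in 2i medium and injected into 8-cell embryos. The mothers drank water with 2 mg/mL doxycycline and 5% sucrose for 24 hours. Embryos were collected at E8.5 and staged at E7.75 because they lagged by about a day, their ESC contribution was checked, and they were frozen. Libraries followed the Geo-seq protocol, a full-length method for small RNA inputs, with 10 cycles of cDNA pre-amplification and 0.5 ng of cDNA per Nextera XT library, read as 100 bp paired ends. Such libraries carry no molecular identifiers, so pre-amplified copies of a molecule are counted as separate reads.

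The deposited files hold whole-number counts per Ensembl gene, not normalized. Per the submitters' processing notes, STAR, featureCounts of the Subread package and the builds GRCm38 and mm10 were used. Their versions, the annotation release and the strand setting are not given in the sources used here. Because the strand setting is not known, reads of a gene and of an overlapping gene on the other strand cannot be told apart. The Nextera kit itself does not mark strand. Exons of other genes cover part of the exon bases of 24 of the 108 named genes, and over 20% in 4 of them (Apoa4, Rarb, Shh and Tsix), whose values are uncertain.

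Each file lists 39179 genes. Symbols, biotypes, positions, transcript lengths and GC contents were taken from GENCODE vM21 on GRCm38, which holds 37693 (96.2%) of the IDs; the others took 0.179% to 0.210% of the counts of a library. Total counts ran from 21267116 to 30434442 per embryo, so a count of 3 corresponds to 0.0986 to 0.141 CPM. That floor covers counting error only. Log2 CPM of the 2 embryos of a group correlated across genes at 0.982 in FLAG-Lhx1 and 0.978 in FLAG-Lhx1-mt, and between groups at 0.965 to 0.970. Chi-square per degree of freedom between libraries was 31.6 to 124, so no 2 libraries agree within sampling noise, and each was used as 1 replicate.

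The choices that follow were made before the data were examined, unless stated otherwise. Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 15822, and libraries were scaled by TMM. The groups were compared in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F test (estimateDisp, glmQLFit, glmQLFTest) in a model with group only. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 folds are FLAG-Lhx1 minus FLAG-Lhx1-mt. Their standard errors were derived from the test, as the size of the log2 fold over the square root of its F statistic. The biological coefficient of variation was 18.2%. The labels say that RNA came from individual embryos, so p-values rest on the spread between 2 embryos per group. With 2 residual and 13.4 prior degrees of freedom, the variance of a gene was mostly borrowed from other genes. CPM are scaled by TMM, and means are given with the SD of 2 embryos.

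Gene lists (34) for pluripotency, cell types of the gastrula and extraembryonic tissues, signalling pathways, LHX1 partners, maternal cells, RNA quality and embryo sex were written down from general knowledge. None was chosen on these samples. Some share members: the streak list shares 4 genes with the head organizer list and 5 with the caudal epiblast list. Lists with 5 or more tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, adjusted over the lists. Members are counted at an adjusted p under 0.05 over all tested genes and adjusted over the list alone.

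Named genes were fixed by rule. They are Lhx1; the 12 called protein-coding genes with the largest rise and the 12 with the largest fall among those with a mean of 5 CPM or more and no overlap between the groups, leaving out predicted genes; up to 4 called members of each list by p, or the 2 with the smallest p where none was called; 12 genes named in advance (Otx2, Hesx1, Gsc, Dkk1, Cer1, Foxa2, Pou5f1, Nanog, T, Nodal, Lefty1 and Six3); and the genes of X inactivation and the Y chromosome. Counts of named genes include 2 that the rule picked and the text leaves out. Chance alone gives 33.3% of genes without overlap between 2 groups of 2, and 52.2% of the tested genes had none. Members of a list named beyond these, namely Epcam and Ttr, were added after the values were seen, as was the gene model Gm42418.

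The procedure was tested on simulated data, with counts drawn for the 15822 genes from the means and library sizes of these embryos. Changed genes and list members were drawn only from genes with a mean count over 20. In the simulated comparison of FLAG-Lhx1 with FLAG-Lhx1-mt, edgeR recovered 52% of 100 genes changed by a log2 fold of 1 and 85% of 100 changed by 2, and 13 of its 150 calls were false. Camera called 5 of 5 shifted lists and 0 of 20 unshifted ones at the preset correlation and 0 of 5 at an estimated one, while fry called 5 of 5 and 2 of 20.

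Alternatives tried were DESeq2 size factors and upper-quartile scaling in place of TMM; no count filter and a stricter one (mean count of 10 and over 1 CPM in 2 libraries); the Wald test of DESeq2 1.42.0; limma-voom; edgeR's legacy form of the test, which is the default of this version and so the same fit; the replicate number as a block; removal of mitochondrially encoded, ribosomal protein and haemoglobin genes; an estimated correlation and fry for the lists; and each embryo left out in turn, where the lone embryo of a group is assumed to vary like the other group. Added after seeing the data were the newer form of edgeR's test, removal of 13 gene models that share at least 40 16-base words with the satellite-like model Gm10800, and offsets per library for GC content and transcript length (lowess, span 0.3), for which 99.1% of the tested genes have values. The embryoid body, DamID and ATAC-seq data and the embryos of another stage that the design of the series mentions were not analysed here.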

Results

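Gene expression was measured by RNA sequencing of 4 individual mouse embryos at E7.75, when gastrulation is under way and the head begins to form. The embryos were chimeras: embryonic stem cells (ESCs) were injected into 8-cell host embryos, and embryos with a high share of ESC descendants were used. The ESCs carried a doxycycline-inducible, FLAG-tagged form of LHX1, a LIM homeodomain transcription factor. In 2 embryos it was FLAG-Lhx1, and in the other 2 it was FLAG-Lhx1-mt, which the labels also write with a deletion sign. Which part of the protein is missing is not given in the sources used here. Doxycycline was given to the mothers for 24 hours before collection. The deposited gene counts summed to 25272436 and 21267116 in FLAG-Lhx1 replicates 1 and 2, and to 23088545 and 30434442 in FLAG-Lhx1-mt replicates 1 and 2. The title of the series names pluripotency, signalling and the specification of the head, and the comparison of the 2 forms addresses which genes differ when the intact rather than the altered form is induced.

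In FLAG-Lhx1 embryos, 7 of 12 tested genes of the anterior neural plate and 7 of 15 of somite-forming mesoderm were higher than in FLAG-Lhx1-mt embryos, and 10 of 20 pluripotency genes and 6 of 16 primitive streak genes were lower. These 4 lists were called by limma's camera at a preset correlation but not at an estimated one (adjusted p = 0.468 to 0.566 with an estimated correlation). In addition, 11 of 18 visceral endoderm genes were lower. Among the called protein-coding genes with a mean of at least 5 CPM (counts per 1000000 counts), the largest rise was that of Aldh1a2, which encodes the enzyme that makes retinoic acid in the early trunk. Its level was 39.4 ± 14.8 CPM in FLAG-Lhx1 and 0.809 ± 0.557 CPM in FLAG-Lhx1-mt (SD, n = 2 each), a log2 fold of 5.67 ± 0.38 (SE, edgeR adjusted p = 8.57e-07). The largest fall among them was that of Tdgf1, which encodes the NODAL co-receptor CRIPTO, from 131 ± 64.0 CPM in FLAG-Lhx1-mt to 4.75 ± 1.82 CPM in FLAG-Lhx1 (SD, n = 2 each). Its log2 fold was -4.76 ± 0.32 (SE, adjusted p = 8.57e-07). Aldh1a2 (ENSMUSG00000013584) lies on chromosome 9 at 71215789 to 71296243 and Tdgf1 (ENSMUSG00000032494) on chromosome 9 at 110939603 to 110946158 of GRCm38.

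Lhx1 itself (ENSMUSG00000018698, chromosome 11 at 84518284 to 84525535) was not called between the groups. It had 129 and 114 CPM in FLAG-Lhx1 replicates 1 and 2, and 126 and 98.5 CPM in FLAG-Lhx1-mt replicates 1 and 2, a log2 fold of 0.11 ± 0.16 (SE, edgeR adjusted p = 0.733). Counts per gene do not separate the transgene from the endogenous gene, so this level does not check which form an embryo carried. No uninduced embryo was analysed here, so the size of the induction is not known.

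Of 15822 genes tested, edgeR called 976 at an adjusted p under 0.05, of which 415 were higher and 561 lower in FLAG-Lhx1. At least a 2-fold change was found for 422 of them, 214 higher and 208 lower. After Aldh1a2, the genes ranked next by rise were Qrfpr, a neuropeptide receptor gene (log2 fold 4.45), the forkhead gene Foxd4 (4.28), Fos (3.85), the mesenchymal homeobox gene Prrx1 (3.44) and Dach1 (3.15). They were followed by Tpm3-rs7 (3.00), Hesx1 (2.80), Six3 (2.42), Ermn (2.37), Gal, which encodes the peptide galanin (2.35), and Ptn, which encodes the growth factor pleiotrophin (2.32). Tpm3-rs7 is a related copy of Tpm3, and reads of the 2 genes may have been split between them, so its value is uncertain. After Tdgf1, the genes ranked by fall were Mixl1 (-3.68), Eomes (-3.12), Utf1 (-2.97), the amino acid transporter gene Slc7a3 (-2.78), Mal2 (-2.72), Pga5 (-2.60), Wnt3 (-2.58), Enpp3 (-2.16), Arl4d (-2.16), Klhl6 (-2.14) and Lefty2 (-2.07). The log2 fold of each of these 24 genes kept its sign with each embryo left out in turn. They were picked for large folds without overlap between the groups, so this was largely fixed in advance. The log2 fold of Gal was 3.70 and 1.60 without FLAG-Lhx1-mt replicates 1 and 2, and that of Eomes was -1.94 without FLAG-Lhx1-mt replicate 2. DESeq2's Wald test did not call Gal (adjusted p = 0.101).

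**Figure D1:**
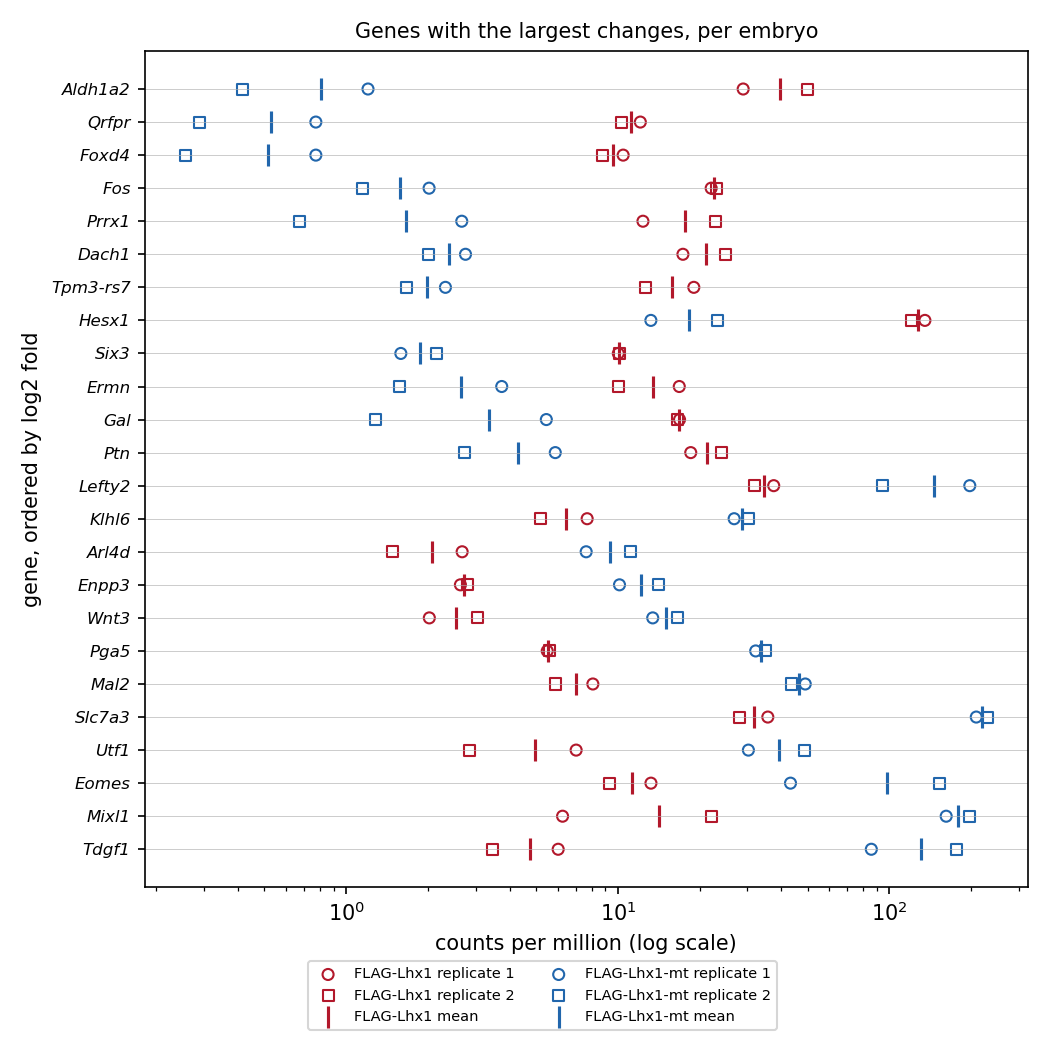
CPM (log scale) of the 24 genes with the largest log2 folds among the called protein-coding genes with a mean of at least 5 CPM, ordered by log2 fold. Circles and squares are replicates 1 and 2, red for FLAG-Lhx1 and blue for FLAG-Lhx1-mt, and vertical bars are the means of 2 embryos. The 2 groups do not overlap for any of these genes, a condition for being shown.

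The number of called genes moved with the embryos used. It was 628 without FLAG-Lhx1 replicate 1, 521 without FLAG-Lhx1 replicate 2, 1648 without FLAG-Lhx1-mt replicate 1 and 1553 without FLAG-Lhx1-mt replicate 2, and 295 genes were called with the same sign in all 4 of these fits. Across the tested genes, which are not independent replicates, the log2 fold rose with transcript length (Spearman's rho = 0.245) and fell with GC content (rho = -0.163). The median transcript length was 4067 bases for genes called higher and 2000 bases for genes called lower. Offsets for length and GC content left 598 calls, 274 higher and 324 lower, of which 521 were shared with the 976. Upper-quartile normalization called 472 genes higher and 395 lower, so that higher genes made up 54.4% of the calls, against 42.5% with TMM. With 2 embryos per group, an exact two-sided permutation test of a single gene cannot give a p below 0.333, so the calls rest on edgeR's model of the spread over all genes.

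Genes of core and formative pluripotency were lower in FLAG-Lhx1. Of 20 tested members, 10 fell, 2 rose and 8 did not pass; adjusted over the list alone, 11 fell and 2 rose. Besides Tdgf1, Utf1 and Slc7a3, the members that fell included Pou5f1, which encodes OCT4, at 5.56 ± 0.67 CPM against 18.9 ± 1.61 CPM (SD, n = 2 each; log2 fold -1.76 ± 0.23, SE, edgeR adjusted p = 0.000487), and Nanog (-1.50 ± 0.27, adjusted p = 0.00494). Sox2, which is also a neural progenitor gene, rose (1.05 ± 0.23, adjusted p = 0.0144), but this call was lost without FLAG-Lhx1 replicate 1 (log2 fold 0.75). The list was called lower by limma's camera at a preset correlation (median log2 fold -0.87; adjusted p = 7.48e-05, adjusted p = 0.553 with an estimated correlation).

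Genes of naive pluripotency were not called as a list (median log2 fold -0.33; camera adjusted p = 0.753). Their median was -0.15 and -0.19 without FLAG-Lhx1 replicates 1 and 2 and -0.08 without FLAG-Lhx1-mt replicate 2. Of 13 tested members, Klf4 rose (1.55 ± 0.33, SE, edgeR adjusted p = 0.0125) and Fgf4 fell (-1.67 ± 0.41, adjusted p = 0.0276), and the counts were the same adjusted over the list alone. The call of Klf4 was lost without FLAG-Lhx1 replicate 2 (log2 fold 1.44), and that of Fgf4 without FLAG-Lhx1-mt replicate 1 (-0.75), with DESeq2, with limma-voom and with the GC and length offsets. Of 10 tested genes of primordial germ cells, Nanog fell and none rose, or 1 fell and 2 rose adjusted over the list alone; the list was not called (median -0.11, -0.18 to 0.10 with 1 embryo left out; adjusted p = 0.772).

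Genes of the primitive streak and nascent mesoderm, where epiblast cells leave the epithelium, were lower in FLAG-Lhx1: 6 of 16 tested members fell and none rose, and adjusted over the list alone 9 fell. Mixl1, a homeobox gene of the streak, was at 14.2 ± 11.2 CPM in FLAG-Lhx1 against 179 ± 24.9 CPM in FLAG-Lhx1-mt (SD, n = 2 each; log2 fold -3.68 ± 0.37, SE, edgeR adjusted p = 3.95e-05). Eomes was at 11.3 ± 2.78 CPM against 98.1 ± 77.6 CPM, and the 2 FLAG-Lhx1-mt embryos differed, with 43.2 CPM in replicate 1 and 153 CPM in replicate 2. Wnt3 and the early mesoderm gene Mesp1 (-1.47 ± 0.19, adjusted p = 0.000404) also fell. T, which encodes brachyury, fell by 0.70 on the log2 scale (SE 0.20; adjusted p = 0.0481), a call lost without FLAG-Lhx1 replicate 2 (-0.50), without FLAG-Lhx1-mt replicate 1 (-0.33), with upper-quartile normalization and with the GC and length offsets. The list was called lower (median -0.89, camera adjusted p = 7.48e-05, adjusted p = 0.468 with an estimated correlation).

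Among signalling genes, 4 of 17 tested members of the NODAL and activin list fell and none rose; adjusted over the list alone, 7 fell and 2 rose. Nodal, the ligand, was at 1.39 ± 0.24 CPM in FLAG-Lhx1 against 7.65 ± 2.19 CPM in FLAG-Lhx1-mt (SD, n = 2 each; log2 fold -2.45 ± 0.35, SE, edgeR adjusted p = 0.000934). The others were Tdgf1, the NODAL antagonist gene Lefty2 and Pmepa1, whose call was lost without FLAG-Lhx1 replicate 1 (-2.78) and without FLAG-Lhx1-mt replicate 2 (-1.58), with upper-quartile normalization, with limma-voom and with the GC and length offsets. Lefty1 stayed below the count filter, with 15 counts in the FLAG-Lhx1 embryos together and 10 in the FLAG-Lhx1-mt embryos. The list as a whole was not called (median -0.31, camera adjusted p = 0.123), except without FLAG-Lhx1-mt replicate 1 (median -0.23, adjusted p = 0.0303). Its median was -0.18 without FLAG-Lhx1 replicate 2 and -0.15 without FLAG-Lhx1-mt replicate 2.

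Of 20 tested genes of FGF and ERK signalling, 6 fell and 2 rose, or 10 and 4 adjusted over the list alone. Fgf5 (log2 fold -1.79 ± 0.30, SE, edgeR adjusted p = 0.00278) and the pathway's feedback and target genes Dusp6 (-0.99 ± 0.16, adjusted p = 0.00231) and Etv5 (-1.20 ± 0.20, adjusted p = 0.0029) fell. The receptor gene Fgfr2 (2.21 ± 0.20, adjusted p = 1.42e-05) and Egr1 (1.79 ± 0.42, adjusted p = 0.0196), which is also on this list, rose. The call of Egr1 was lost without FLAG-Lhx1 replicate 2 (1.57). The fold of Fgf5 was -0.999 without FLAG-Lhx1-mt replicate 2, and DESeq2 did not call it (adjusted p = 0.0588). The list missed the threshold (median -0.80, camera adjusted p = 0.0565) and passed it without FLAG-Lhx1-mt replicate 1 (0.00346), with no count filter (0.0132), with upper-quartile normalization (0.0426) and with the GC and length offsets (0.0455). Without FLAG-Lhx1-mt replicate 2 its median was -0.37 (adjusted p = 0.137). Of 23 WNT signalling genes, Wnt3 and Dkk1 fell and Sfrp1 (1.03 ± 0.16, adjusted p = 0.00203), Wnt6 and Rspo3 rose, or 4 fell and 3 rose adjusted over the list alone. Their median was -0.08 (-0.25 to 0.30 with 1 embryo left out) and the list was not called (adjusted p = 0.796). The call of Rspo3 was lost without FLAG-Lhx1 replicate 2 (0.70). Of 21 BMP signalling genes none passed edgeR's test, over all genes or adjusted over the list alone (median 0.01, camera adjusted p = 0.739); 5 had an unadjusted p under 0.05, and DESeq2 called 0 and limma-voom 1. The smallest p-values were those of Nog (log2 fold 1.86; edgeR adjusted p = 0.0627) and Gata2 (1.42; adjusted p = 0.0896), and Gata2 was called without FLAG-Lhx1-mt replicate 2 (1.83). Nog was called without FLAG-Lhx1 replicate 2 (2.07), without FLAG-Lhx1-mt replicate 1 (3.21), by limma-voom, by the newer form of edgeR's test, with no count filter and without the satellite-like genes.

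Genes of the anterior neuroectoderm, the source of the forebrain, were higher in FLAG-Lhx1. Of 12 tested members 7 rose and none fell; adjusted over the list alone 9 rose. Hesx1, a homeobox gene needed for forebrain and pituitary development, was at 128 ± 10.2 CPM in FLAG-Lhx1 against 18.2 ± 7.05 CPM in FLAG-Lhx1-mt (SD, n = 2 each; log2 fold 2.80 ± 0.22, SE, edgeR adjusted p = 2.78e-06). Six3, a forebrain and eye homeobox gene, was at 10.1 ± 0.06 CPM against 1.87 ± 0.39 CPM (adjusted p = 0.000289), and the forebrain zinc finger gene Fezf1 at 7.04 ± 1.70 CPM against 0.219 ± 0.006 CPM (log2 fold 4.97 ± 0.45; adjusted p = 1.4e-05). Fezf2 had 30 counts in the FLAG-Lhx1 embryos together and 0 in the FLAG-Lhx1-mt embryos. That makes it at least 11.9-fold higher if the latter held up to 3 counts together. Without FLAG-Lhx1 replicate 2, Fezf2 fell below the count filter and was not tested. Otx2, a head gene already on in the epiblast, was not called (59.9 ± 5.40 CPM against 70.4 ± 18.03 CPM; log2 fold -0.23 ± 0.18; adjusted p = 0.482). The list had a median log2 fold of 1.94 (camera adjusted p = 5.13e-07, adjusted p = 0.468 with an estimated correlation).

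The list of anterior mesendoderm and head organizer genes moved both ways and was not called (median -0.24, camera adjusted p = 0.704). Its median was -0.16 without FLAG-Lhx1 replicate 2 and -0.07 without FLAG-Lhx1-mt replicate 2. Of 15 tested members Six3 and Shisa2, an inhibitor of WNT and FGF signalling (1.64 ± 0.19, SE, edgeR adjusted p = 0.000119), rose and Mixl1, Eomes, Cer1 and Dkk1 fell, or 3 rose and 4 fell adjusted over the list alone. Cer1 (-0.72 ± 0.18, adjusted p = 0.0283) and Dkk1 (-0.71 ± 0.17, adjusted p = 0.0196) encode secreted antagonists made by the head organizer. Both calls were lost without FLAG-Lhx1 replicate 2 (-0.45 and -0.64), that of Dkk1 also without FLAG-Lhx1 replicate 1 (-0.80) and that of Cer1 with the GC and length offsets. Foxa2 was not called (0.44 ± 0.22, adjusted p = 0.267), and Gsc stayed below the filter, with 13 counts in the FLAG-Lhx1 embryos and 48 in the FLAG-Lhx1-mt embryos, 46 of them in replicate 2.

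Of 15 genes of LHX1 partners and LIM domain factors 4 rose and none fell, with the same counts adjusted over the list alone. They were Kctd1 (1.48 ± 0.30, SE, edgeR adjusted p = 0.00865), Isl1, Lhx2 and Lmo1. The call of Lhx2 was lost without FLAG-Lhx1 replicate 1 (1.43) and that of Lmo1 without FLAG-Lhx1 replicate 1 (1.36), FLAG-Lhx1 replicate 2 (1.17) or FLAG-Lhx1-mt replicate 1 (0.94). The fold of Isl1 was 2.45 and 0.92 without FLAG-Lhx1-mt replicates 1 and 2, and DESeq2 did not call it. The list was not called (median 0.19, camera adjusted p = 0.123), except without FLAG-Lhx1 replicate 2 (median 0.48, adjusted p = 0.0209) and with the GC and length offsets (0.39, adjusted p = 0.023). Its median was -0.03 without FLAG-Lhx1 replicate 1 and 0.39 without FLAG-Lhx1-mt replicate 1.

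Genes of SHH signalling and of the node and notochord were called higher. Of 14 SHH genes, Shh and Gli3 (0.81 ± 0.17, SE, edgeR adjusted p = 0.012) rose and none fell, or 3 rose adjusted over the list alone (median 0.45, camera adjusted p = 0.00527, adjusted p = 0.553 with an estimated correlation). Shh, the midline signal, was low, at 2.21 ± 0.39 CPM against 0.107 ± 0.15 CPM (SD, n = 2 each, log2 fold 4.47 ± 0.83, edgeR adjusted p = 0.00577). Its fold was 3.32 without FLAG-Lhx1-mt replicate 2. FLAG-Lhx1-mt replicate 2 had 0 counts of Shh, so the fold without FLAG-Lhx1-mt replicate 1 has no exact size. Annotated genes on the other strand cover 28.3% of the exon bases of Shh, so some of its reads may belong to them. Of 13 node and notochord genes, Sox9 (2.20 ± 0.20, adjusted p = 1.42e-05) and Shh rose and T fell, or 3 rose and 1 fell adjusted over the list alone; Sox9 is also a gene of neural crest. That list (median 0.44, camera adjusted p = 0.0183, adjusted p = 0.553 with an estimated correlation) was not called without FLAG-Lhx1 replicate 1 (median 0.25, adjusted p = 0.272) or FLAG-Lhx1-mt replicate 2 (0.355), or with no count filter (0.127).

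Of 15 genes of surface ectoderm and neural crest, Sox9, Snai2 (2.46 ± 0.38, SE, edgeR adjusted p = 0.00162) and Tfap2a rose and Foxd3 fell, with the same counts adjusted over the list alone. Foxd3 is also a gene of the epiblast; it had 129 counts in the FLAG-Lhx1-mt embryos and 10 in the FLAG-Lhx1 embryos. Its call was lost without FLAG-Lhx1-mt replicate 2 (log2 fold -1.35), with limma-voom and with the GC and length offsets. The call of Tfap2a was lost without FLAG-Lhx1 replicate 1 (1.49), FLAG-Lhx1 replicate 2 (1.21) or FLAG-Lhx1-mt replicate 2 (1.04) and with the offsets. The list was not called (median 0.63, camera adjusted p = 0.123), except with a stricter count filter (median 0.31, adjusted p = 0.0252) and with the offsets (0.0146). Its median was 0.27 and 0.21 without FLAG-Lhx1 replicates 1 and 2 and 0.36 without FLAG-Lhx1-mt replicate 2.

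Genes of paraxial mesoderm and somites were higher in FLAG-Lhx1: 7 of 15 tested members rose and none fell, and adjusted over the list alone 8 rose and 1 fell. Besides Aldh1a2, they included the forkhead genes Foxc1 (21.7 ± 0.41 CPM against 6.23 ± 3.39 CPM, SD, n = 2 each; log2 fold 1.81 ± 0.30, SE, edgeR adjusted p = 0.00263) and Foxc2 (1.76 ± 0.29, adjusted p = 0.00244), and Pax3 (3.48 ± 0.64, adjusted p = 0.00551), which is used in somites and in the dorsal neural tube. The list had a median log2 fold of 1.71 (camera adjusted p = 0.000524, adjusted p = 0.566 with an estimated correlation), which was 1.09 without FLAG-Lhx1-mt replicate 2.

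Genes of retinoic acid signalling were called higher, with 4 of 14 tested members up and 1 down, or 6 up and 1 down adjusted over the list alone. Crabp2, which encodes a retinoic acid carrier, was at 161 ± 64.0 CPM against 35.9 ± 9.76 CPM (SD, n = 2 each; log2 fold 2.17 ± 0.24, SE, edgeR adjusted p = 8.58e-05), and the receptor gene Rarb also rose (2.26 ± 0.37, adjusted p = 0.00261), although genes on the other strand cover 38.4% of its exon bases. Cyp26a1, which encodes an enzyme that degrades retinoic acid, fell (-1.50 ± 0.19, adjusted p = 0.000283). The list (median 0.62, camera adjusted p = 0.0197, adjusted p = 0.553 with an estimated correlation) was not called without FLAG-Lhx1 replicate 2 (0.0545) or FLAG-Lhx1-mt replicate 2 (0.0525). Its median was 1.00 without FLAG-Lhx1-mt replicate 1.

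The list of Hox genes, which pattern the trunk, was called higher. Hoxa2 rose (1.95 ± 0.46, SE, edgeR adjusted p = 0.0196), a call lost without FLAG-Lhx1 replicate 2 (1.35). The list of 8 tested genes (median 1.26, camera adjusted p = 0.0253, adjusted p = 0.553 with an estimated correlation) was not called without FLAG-Lhx1 replicate 2 (median 0.49, adjusted p = 0.231) or FLAG-Lhx1-mt replicate 1 (0.60, adjusted p = 0.0524), or with no count filter (0.66, adjusted p = 0.0701). Its median was 1.99 without FLAG-Lhx1-mt replicate 2. Of 14 genes of caudal epiblast and neuromesodermal cells, Sox2 and Nkx1-2 (1.58 ± 0.34, adjusted p = 0.0144) rose and Cyp26a1 and T fell, or 2 rose and 4 fell adjusted over the list alone. Nkx1-2 had folds of 2.65 and 0.94 without FLAG-Lhx1-mt replicates 1 and 2 and was not called by DESeq2, and the call of Sox2 was lost without FLAG-Lhx1 replicate 1 (0.75). T lost its call without FLAG-Lhx1 replicate 2 (-0.50) or FLAG-Lhx1-mt replicate 1 (-0.33). That list was not called, and its median (0.22) was above 0 while camera's direction was down (adjusted p = 0.707). The median was -0.47 without FLAG-Lhx1 replicate 2 and 0.08 without FLAG-Lhx1-mt replicate 2.

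Genes of visceral and yolk sac endoderm, the extraembryonic layer that feeds the early embryo, were lower in FLAG-Lhx1. Of 18 tested members 11 fell, none rose and 7 did not pass; adjusted over the list alone 17 fell. The apolipoprotein gene Apoa1 was at 428 ± 11.2 CPM against 1054 ± 75.6 CPM (SD, n = 2 each; log2 fold -1.30 ± 0.15, SE, edgeR adjusted p = 0.000119), Apoe at 496 ± 50.3 CPM against 1300 ± 268 CPM (-1.39 ± 0.17, adjusted p = 0.000268), and Car4, a carbonic anhydrase gene, at 590 ± 20.8 CPM against 1217 ± 248 CPM (-1.04 ± 0.16, adjusted p = 0.00196). Apoa4 fell as well (-1.30), but genes on the other strand cover 69.8% of its exon bases. The list's folds lay between -1.39 and -0.22 (median -0.64, camera adjusted p = 2.56e-08, adjusted p = 0.468 with an estimated correlation), so these markers of another tissue moved with the groups beside the pluripotency, streak, anterior neural and paraxial genes.

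Of 15 genes of definitive endoderm and gut, Cldn6 (-1.43 ± 0.15, SE, edgeR adjusted p = 8.14e-05), Trh (-1.66 ± 0.21, adjusted p = 0.00033), Gata4 and Epcam fell and Cpm rose, or 5 fell and 1 rose adjusted over the list alone. The fold of Cpm was 2.00 and 0.83 without FLAG-Lhx1-mt replicates 1 and 2, and the call of Gata4 was lost without FLAG-Lhx1 replicate 2 (-0.93). The list was not called (median -0.27, -0.42 to -0.12 with 1 embryo left out; camera adjusted p = 0.252). Of 12 genes of extraembryonic ectoderm and trophoblast, Rhox5 fell (-0.76 ± 0.15, adjusted p = 0.00954) and none rose, or 2 fell adjusted over the list alone, and the call of Rhox5 was lost without FLAG-Lhx1 replicate 1 (-0.62). That list was not called either, with a median of 0.08 (-0.24 to 0.30 with 1 embryo left out) and a direction of down (adjusted p = 0.929).

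Genes of cardiac and lateral plate mesoderm moved both ways: of 15 tested members Myl7, an atrial myosin light chain gene (-1.39 ± 0.24, SE, edgeR adjusted p = 0.00374), and Gata4 fell and Isl1 rose, or 2 fell and 2 rose adjusted over the list alone. The fold of Myl7 was -0.81 without FLAG-Lhx1-mt replicate 1. The fold of Isl1 was 2.45 and 0.92 without FLAG-Lhx1-mt replicates 1 and 2, and the call of Gata4 was lost without FLAG-Lhx1 replicate 2 (-0.93). The median log2 fold was 0.01 (camera adjusted p = 0.81). Of 10 genes of allantois and extraembryonic mesoderm, Vim (0.98 ± 0.15, adjusted p = 0.0014) and Ahnak (1.52 ± 0.26, adjusted p = 0.00357) rose and none fell, or 4 rose adjusted over the list alone. Vim and Ahnak are used widely in mesenchymal cells and are not specific to the allantois. That list was called higher (median 0.70, camera adjusted p = 0.00192, adjusted p = 0.549 with an estimated correlation). Its median was 0.40 without FLAG-Lhx1 replicate 1 and 1.07 without FLAG-Lhx1-mt replicate 2. None of the 7 tested genes of primitive blood and none of the 9 of endothelium passed edgeR's test, over all genes or adjusted over the list alone; 1 and 2 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Their camera adjusted p-values were 0.537 (median 0.50) and 0.519 (median -0.03, -0.19 to 0.55 with 1 embryo left out, with a mean of 0.43 and a direction of up). The blood median was -0.45 and -0.11 without FLAG-Lhx1 replicates 1 and 2 and -0.18 without FLAG-Lhx1-mt replicate 1. The smallest p-values belonged to Itga2b (log2 fold 1.71) and Tal1 (0.86), and to Fli1 (1.31) and Pecam1 (1.63); Tal1 (1.78) and Pecam1 (2.98) were called without FLAG-Lhx1-mt replicate 2.

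**Figure D2:**
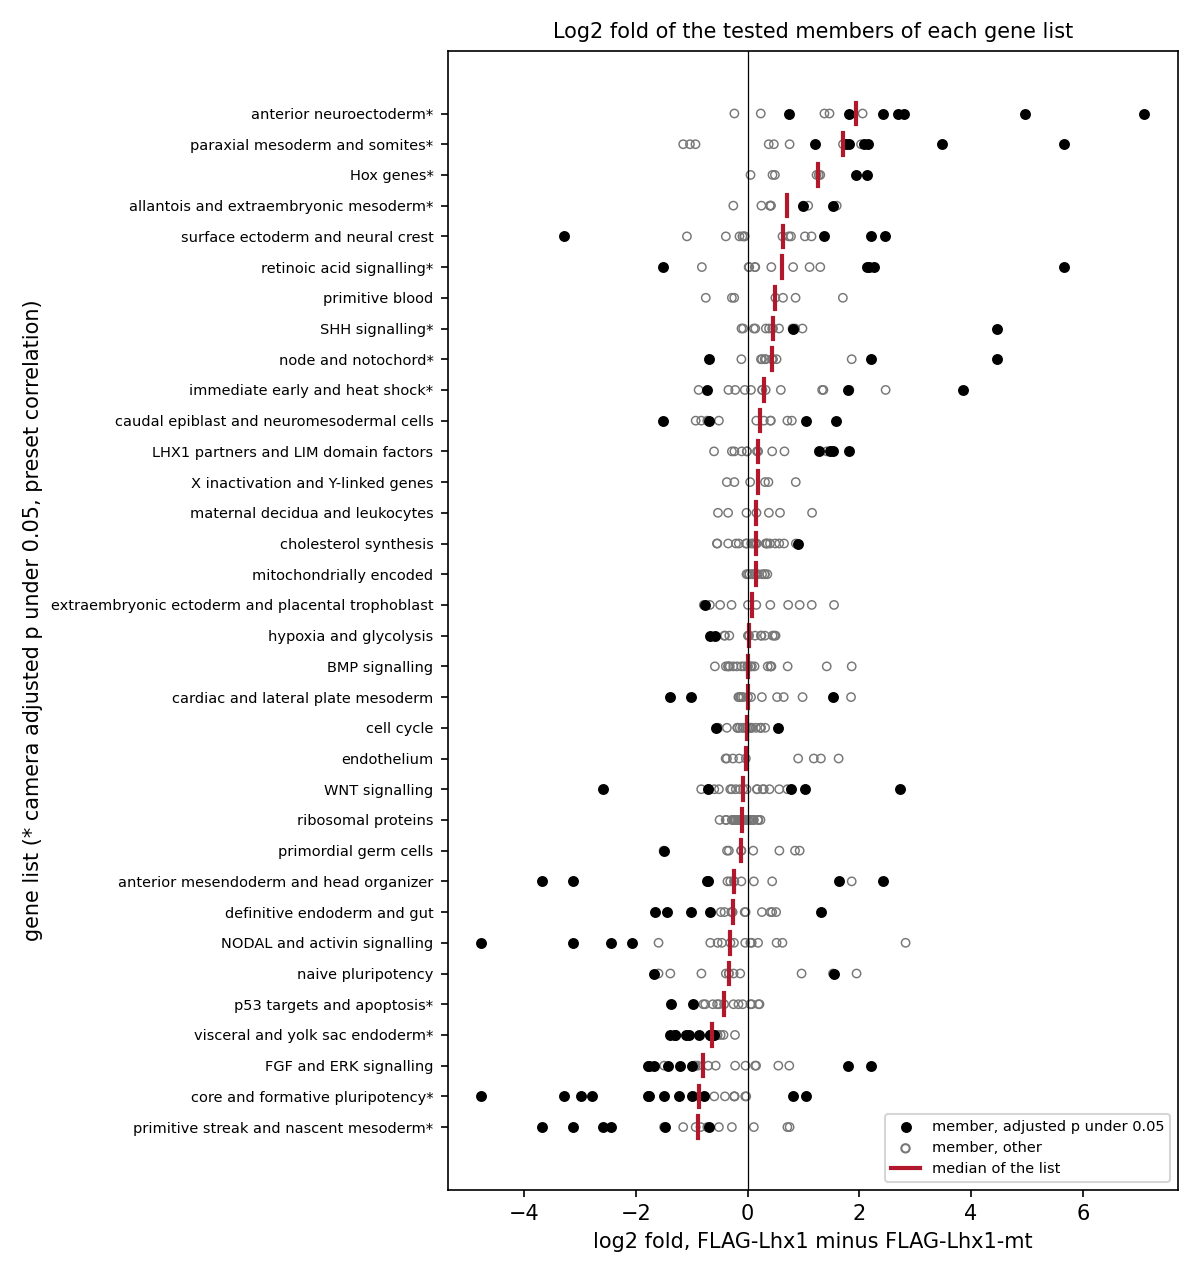
Log2 fold (FLAG-Lhx1 minus FLAG-Lhx1-mt, 2 embryos each) of every tested member of the 34 gene lists, ordered by the median of the list (red bar). Filled points are genes with an edgeR adjusted p under 0.05 and open points are the rest, and stars mark the 12 lists called by camera at a preset correlation of 0.01. Medians run from -0.89 for the primitive streak to 1.94 for the anterior neuroectoderm.

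Of 16 immediate early and heat shock genes, a list fixed as a sign of RNA quality, Fos, which encodes part of the AP-1 transcription factor (22.5 ± 0.66 CPM against 1.58 ± 0.61 CPM, SD, n = 2 each; edgeR adjusted p = 2.78e-06), and Egr1 (log2 fold 1.79 ± 0.42, SE, adjusted p = 0.0196) rose and the chaperone gene Dnajb1 fell (-0.73), or 4 rose and 2 fell adjusted over the list alone. The call of Egr1 was lost without FLAG-Lhx1 replicate 2 (1.57), and that of Dnajb1 without FLAG-Lhx1 replicate 1 (-0.50), with upper-quartile normalization and with the GC and length offsets. The list (median 0.30, camera adjusted p = 0.0263, adjusted p = 0.553 with an estimated correlation) was not called without FLAG-Lhx1 replicate 1 (median 0.18, adjusted p = 0.155) or FLAG-Lhx1-mt replicate 2 (adjusted p = 0.0786). Its median was 0.45 without FLAG-Lhx1-mt replicate 1. Of 15 genes of p53 targets and apoptosis, Aen (-0.97 ± 0.16, adjusted p = 0.00244) and Phlda3 (-1.36) fell and none rose, or 5 fell adjusted over the list alone, and the call of Phlda3 was lost without FLAG-Lhx1 replicate 1 (-1.36) or replicate 2 (-1.38) and with the offsets. That list (median -0.42, camera adjusted p = 0.0123, adjusted p = 0.553 with an estimated correlation) was not called in any of the 4 fits that left out an embryo (adjusted p 0.0525 to 0.225), with medians of -0.25 and -0.26 without FLAG-Lhx1-mt replicates 1 and 2.

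Genes of metabolism and division showed small changes, and none of their lists was called. Of 16 genes of hypoxia and glycolysis, Eno1 (-0.67 ± 0.15, SE, edgeR adjusted p = 0.0179) and Pfkl (-0.58) fell, or 2 fell and 1 rose adjusted over the list alone (median 0.03, camera adjusted p = 0.938). The list of 20 genes of cholesterol synthesis had a median of 0.15 (camera adjusted p = 0.333) and was called without FLAG-Lhx1-mt replicate 2 (median 0.68, adjusted p = 0.000336). Its median was -0.14 without FLAG-Lhx1-mt replicate 1. Of 22 cell cycle genes Bub1 (0.54) rose and Ccne1 (-0.57) fell, or 1 rose and 3 fell adjusted over the list alone (median -0.02, -0.11 to 0.05 with 1 embryo left out; adjusted p = 0.755). The calls of Eno1, Pfkl, Bub1 and Ccne1 were lost with the GC and length offsets (log2 fold -0.45, -0.51, 0.39 and -0.35) and without FLAG-Lhx1 replicate 2 (-0.61, -0.57, 0.51 and -0.43). Those of Pfkl and Ccne1 were also lost with upper-quartile normalization and without FLAG-Lhx1-mt replicate 1 (-0.38 and -0.42), those of Pfkl and Bub1 without FLAG-Lhx1 replicate 1 (-0.61 and 0.55), and that of Bub1 without FLAG-Lhx1-mt replicate 2 (0.49).

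Of the 3 lists fixed as signs of RNA quality, that of immediate early and heat shock genes was called at the preset correlation (camera adjusted p = 0.0263, adjusted p = 0.553 with an estimated correlation) but not without FLAG-Lhx1 replicate 1 (0.155) or FLAG-Lhx1-mt replicate 2 (0.0786). Those of mitochondrially encoded and ribosomal protein genes were not called. None of the 11 mitochondrially encoded genes passed edgeR's test (median 0.15, -0.03 to 0.26 with 1 embryo left out; camera adjusted p = 0.391; smallest p for mt-Atp6, log2 fold 0.35, and mt-Co3, 0.30). None of the 40 ribosomal protein genes did (median -0.09, -0.21 to 0.01 with 1 embryo left out; adjusted p = 0.241; smallest p for Rpl18, -0.50, and Rpl13, -0.38), but their list was called lower without FLAG-Lhx1-mt replicate 1 (adjusted p = 0.013) and with no count filter (0.0362). With the GC and length offsets it was called higher (median 0.07, adjusted p = 0.00383). Of 7 tested genes of maternal decidua and leukocytes none passed (median 0.16, -0.24 to 0.24 with 1 embryo left out; adjusted p = 0.753; smallest p for Cryab, 1.16, and Bmp2, -0.35). None of these 3 lists had a call adjusted over the list alone. At an unadjusted p under 0.05 there were 0 mitochondrially encoded, 3 ribosomal protein and 1 maternal gene, and DESeq2 and limma-voom called Rpl18 and none of the others. Rpl18 was also called without FLAG-Lhx1-mt replicate 1 (-0.61), and Rpl18 and Rpl13 with no count filter. Gene models resembling satellite repeats took 9.93% and 17.0% of the counts in FLAG-Lhx1 replicates 1 and 2 and 9.07% and 7.10% in FLAG-Lhx1-mt replicates 1 and 2, and removing them left 1072 calls. The gene model Gm42418 took 0.336% and 0.268% against 0.530% and 0.702%.

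None of the 6 genes of X inactivation and the Y chromosome was called between the groups by edgeR, over all genes or adjusted over the list alone (median 0.18, -0.89 to 1.06 with 1 embryo left out; camera adjusted p = 0.886), nor by DESeq2 or limma-voom; 0 had an unadjusted p under 0.05. Xist, the RNA that coats the inactive X chromosome, was at 29.4 and 1.93 CPM in FLAG-Lhx1 replicates 1 and 2 and at 2.66 and 14.5 CPM in FLAG-Lhx1-mt replicates 1 and 2, and the Y-linked gene Eif2s3y at 2.79, 14.4, 15.8 and 4.28 CPM in the same order. Ddx3y was at 12.9, 14.7, 18.6 and 2.91 CPM, Uty at 2.98, 4.63, 4.47 and 1.69 CPM, and Kdm5d at 0.267, 1.68, 1.76 and 0.128 CPM, so Y-linked genes had counts in each embryo. Tsix was at 0.229, 1.32, 1.33 and 0.639 CPM, and Xist, on the other strand, covers part of the 32.6% of its exon bases that other genes share. With no count filter Xist was called (log2 fold 0.80). With 1 embryo left out, it had a called log2 fold of -2.20 without FLAG-Lhx1 replicate 1, 1.76 without FLAG-Lhx1 replicate 2 and 2.57 without FLAG-Lhx1-mt replicate 2. Eif2s3y had called folds of -1.82, 0.97 and -0.93 without FLAG-Lhx1 replicate 2, FLAG-Lhx1-mt replicate 1 and FLAG-Lhx1-mt replicate 2, and Ddx3y one of 2.24 without FLAG-Lhx1-mt replicate 1.

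By camera at the preset correlation, 12 of the 34 lists were called, 8 higher and 4 lower. None was called with an estimated correlation (adjusted p of 0.468 or more) or by fry, a rotation test of each list alone (smallest adjusted p = 0.0504), which gave 3 and 9 lists at an unadjusted p under 0.05, against 13 at the preset correlation. On simulated data for this comparison, the estimated correlation recovered 0 of 5 shifted lists, and the preset one and fry each recovered 5 of 5. The simulated genes were drawn independently, and all members of a shifted list moved by the same log2 fold of 1. Members of the real lists moved by unequal amounts, so the simulation does not show what power fry has on them. Of the 22 lists not called at the preset correlation, 13 had a median of the other sign in at least 1 fit that left out an embryo.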

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

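The GC and length offsets, the removal of satellite-like genes and the newer form of edgeR's test were chosen after seeing the data. None of the 976 called genes changed sign in any setting, and 261 were called in each of them. Offsets for GC content and transcript length left 598 calls (274 higher, 324 lower). The median size of the log2 fold of the 455 calls that ended was 0.72 before and 0.55 after, with a median SE of 0.18 before and 0.17 after. At the median, the folds of these calls thus shrank while their SE did not grow. That does not hold for each of them: Tfap2a lost its call with a log2 fold of 1.366 before and 1.364 after. With no count filter 952 genes were called lower, out of 1447 from 32825 tested genes; the cause was not tested. Over the 4 fits that left out an embryo, calls ranged from 521 to 1648, those higher from 244 to 831 and those lower from 271 to 977; those fits have fewer embryos, and the cause of the larger counts was not tested. The other settings gave 867 to 1202 calls. With the replicate number as a block, 1138 genes were called (514 higher, 624 lower) and 13 lists, with the FGF and ERK list (adjusted p = 0.0384, median -0.75), Nog (log2 fold 2.04, adjusted p = 0.0126) and Rpl18 (-0.50, adjusted p = 0.0263) gained, and no other call of a named gene or list changed. Same-numbered embryos did not deviate together (r = 0.0156 across genes) and the labels do not pair them.

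Of the 34 lists, 0 were called with an estimated correlation and 0 by fry, against 12 (3, 9 and 13 at an unadjusted p under 0.05); the estimated correlation also missed all 5 shifted lists in the simulation, while fry called them. Elsewhere 9 to 16 lists were called. A sign is counted as reversed only where a fit called the gene or list. That was so for Xist (folds of -2.20 to 2.57 with 1 embryo left out), for Eif2s3y (-1.82 to 0.97) and for the ribosomal protein list with the GC and length offsets (median 0.073, against -0.09); the embryos of a group differ in the first 2 genes, and the cause of the last was not tested. In the counts that follow, a call is not counted as ended where a fit did not test the gene. That was so for Fezf2 without FLAG-Lhx1 replicate 2. DESeq2 gave an adjusted p for only 100 of the named genes, and the stricter count filter kept 101. Losses among the rest are therefore not counted for these 2 settings. Of the 106 named genes tested, 85 were called. Leaving out an embryo ended 11 and 15 of these calls for FLAG-Lhx1 replicates 1 and 2 and 5 and 4 for FLAG-Lhx1-mt replicates 1 and 2; the GC and length offsets ended 13, DESeq2 ended 6, upper-quartile scaling 5 and limma-voom 3. At this depth and with 2 embryos per group, about 52% of changes of a log2 fold of 1 were recovered in the simulation. Genes of low mean count were left out of the simulated changes, so recovery among them is not known. Uncalled genes are therefore not shown to be unchanged.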

Other observations

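The tests of developmental stage and of the share of visceral endoderm were chosen after the results were seen. Within the FLAG-Lhx1-mt group the 2 embryos differed along some of the same genes as the groups, in both directions. Nearer to FLAG-Lhx1 in replicate 1, Eomes was at 43.2 CPM in replicate 1 and 153 CPM in replicate 2, Fgf5 at 44.5 and 110 CPM and Nkx1-2 at 29.9 and 9.14 CPM. Nearer to FLAG-Lhx1 in replicate 2, Lefty2 was at 198 CPM in replicate 1 and 94.6 CPM in replicate 2, T at 239 and 150 CPM and Fgf4 at 18.2 and 6.45 CPM. These 6 genes were picked out after their values were seen. Replicate 1 minus replicate 2, the median log2 difference was -0.27 over the 20 pluripotency genes, -0.26 over the 16 streak genes and -0.41 over the 17 NODAL genes. It was 0.52 over the 15 paraxial genes, -0.11 over the 12 anterior neural genes and -0.76 over the 8 Hox genes. Between the FLAG-Lhx1 embryos, the differences in the same order were 0.213, 0.208, 0.165, -0.043, -0.006 and -0.651. The group difference (FLAG-Lhx1 minus FLAG-Lhx1-mt) of these lists was -0.87, -0.89, -0.31, 1.71, 1.94 and 1.26. Cholesterol synthesis genes were lower in FLAG-Lhx1-mt replicate 1 than in replicate 2, by a median log2 difference of -0.80 over 20 genes. These are values of 2 embryos per group, with no test.

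No family of genes grouped by the stem of its symbol stood out. Of 245 families with 8 or more tested protein-coding genes, none held more called genes than chance after adjustment (one-sided Fisher's exact test, adjusted over families in each direction). The smallest adjusted p was 0.177 for the Car genes, in which Car2, Car4, Car7 and Car14 fell and Car3 and Car12 rose out of 12. The Car genes were picked out after their values were seen.

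The first pattern is that 10 of 20 pluripotency, 6 of 16 streak and 4 of 17 NODAL genes were lower and 7 of 12 anterior neural and 7 of 15 paraxial genes higher in FLAG-Lhx1; the NODAL list was not called (adjusted p = 0.123), nor were the other 4 with an estimated correlation (adjusted p = 0.468 to 0.566). A bias by GC content or transcript length is argued against as the whole cause: 91.2% of the 34 called members of the 5 lists stayed called with the same sign after offsets for both. That the FLAG-Lhx1 embryos were further on in development stays open. The Hox list had a median log2 fold of 1.26 (SE 0.33 over its genes). The Hox median was 0.49 without FLAG-Lhx1 replicate 2 and 0.60 and 1.99 without FLAG-Lhx1-mt replicates 1 and 2. But the median of the cardiac list, which also rises with age, was 0.009 (SE 0.27 over its genes), with members going both ways. These standard errors treat genes of the same 4 embryos as independent and do not measure the spread between embryos. The 4 embryos allow only 3 splits into groups of 2, too few for a share under 0.05. The real split called 976 genes, and the highest of the others called 0 by edgeR (148 and 166 genes at an unadjusted p under 0.05, against 3366). No other tool was run on the splits. Each other split puts 1 embryo of each form in each group. A difference between the forms then widens the spread within groups and lowers the calls. The splits therefore cannot decide whether the difference arose by chance. An effect of the induced form of LHX1 is the difference the design names. It is a hypothesis that cannot be told apart from a difference in stage here. All 4 labels give the same stage, E7.75, and nothing finer is given in the sources used here. The 2 forms were also carried by different ESCs, and litter and the share of ESC descendants in each embryo were not measured here. Differences in these cannot be told apart from an effect of the form either.

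The second pattern is that visceral endoderm genes were lower in FLAG-Lhx1. A lower share of visceral endoderm in those libraries, as from dissection, would lower genes made only there by about the same factor. The folds of the listed genes varied more than their standard errors (Cochran's Q test over n = 18 genes, p = 2.28e-06, weighted mean -0.79). Those errors rest on 2 embryos per group. Ttr was at -0.55 and Apoa1 at -1.30, and all folds of the list lay between -1.39 and -0.22. Members made in other cells too would give unequal folds even under a lower share. The test therefore cannot decide on a lower share, which stays open. A bias by GC content or length stays open for part of the list, since 72.7% of the 11 called genes stayed called with offsets. The median log2 fold of these 11 genes was 0.87 in size before and 0.83 after (median SE 0.17 and 0.14). Counting genes gained as well, 10 members of the list were called lower with offsets. An effect on visceral endoderm itself was not tested, and how far ESC descendants form that layer is not measured in these data.

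The third pattern is the share of satellite-like reads, which was highest in FLAG-Lhx1 replicate 2, at 2.18 times that of the other 3 libraries relative to all other reads. Genomic DNA in that library is a candidate source: reads on 1037 olfactory receptor genes, which are largely silent in embryos, were 1.53 times as frequent there (95% limits 1.45 to 1.63, counting error only). Per 1000000 reads outside the satellite-like genes there were 88.2 such reads there, 63.1 in FLAG-Lhx1 replicate 1 and 45.3 and 62.1 in FLAG-Lhx1-mt replicates 1 and 2. The ratio is smaller than that of the satellite-like reads, so transcription of satellite repeats in that embryo stays open as well, and was not tested. Without FLAG-Lhx1 replicate 2, 521 genes were called, 250 higher and 271 lower.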
